A study of Mus musculus with 6 samples.

How the data were processed

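PRO-seq was done on WT-1 brown adipocytes that, per the labels, spent 2 days in induction medium and 4 days in differentiation medium, received lentiviral shRNA on day 6 (non-targeting or against H2A.Z) and were given vehicle or CL316,243 for 4 hours on day 11. There were 6 libraries, 2 per group. The labels number them as replicates, while the columns of the files carry the letters A and B, which are used here as library names. The mapping from letter to replicate number is not given in the sources used here.

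Adapters were trimmed with cutadapt 1.14 and reads were aligned with Bowtie2 to mm10 and handled with SAMtools 1.3.1, per the submitters' processing notes. The counting rule, the strand of the counts and any spike-in are not given in the sources used here. The authors deposited 2 tables of 23232 entries each, 1 per comparison, with the same 6 columns of normalized counts in both, and all columns of values were used. Per the file headers these deposited values are a normalized signal. Fold changes and their standard errors are given by the authors on the log2 scale and, for the fold change, also as a ratio. The deposited score is the log2 fold change divided by its standard error, and each deposited p-value comes with an adjusted p-value that is missing for some entries.

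The analysis planned before the data were examined was edgeR on counts, with limma on log2(value + 1) as the planned fallback if the files held normalized values, which they did. Every value was a whole multiple of 1 step per library within 0.001, so reads could be recovered by dividing by the step. In the control agonist library B the step lay too near 1 for an automatic check to tell it from rounding, although its values were whole multiples too. The size factors were 1.089 and 0.94 for the vehicle libraries A and B, 1.02 and 0.993 for the control agonist libraries, and 0.902 and 1.1 for the knockdown libraries, and they equalled median-of-ratios factors over the 6 libraries. Normalization of this kind takes most genes as unchanged, and a global change would not be seen. Reads recovered in genes came to 30.88 to 38.58 M per library. Genes with few reads, such as Dio2 at 9.45 normalized counts with vehicle, carry a larger counting error than the others.

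Values were log2 transformed after adding 1, and entries with a mean normalized count of at least 10 over the 4 libraries of a comparison were tested with limma 3.58.1 (trend) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. No minimum fold change was set. Standard deviations are over 2 libraries, and standard errors are limma's. Adjusted p-values in the text are from limma unless another tool is named. Alternatives used edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, other scalings, filters, pseudocounts and thresholds, all 6 libraries in 1 model, the authors' deposited adjusted p, and each library left out in turn.

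The letter was also used as a block. DESeq2 on recovered reads of all 6 libraries with terms for letter and group gave the authors' deposited log2 fold changes to within 0.00031 and 0.00029 in the 2 comparisons, while without the letter the largest differences were 2.8 and 2.1. The authors' own test therefore held the letter as a term. The B minus A differences also correlated across genes between the groups, with r = 0.65, 0.639 and 0.744. Why libraries of a letter deviate together is not given in the sources used here. With 4 libraries and the block, 1 residual degree of freedom was left and the spread was almost wholly borrowed from other genes (prior degrees of freedom Inf and 291), so letter-blocked p-values and standard errors rest on that borrowing.

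Methods were tested on simulated data with known changes added. The simulated letter difference of a gene was the same in every group, so the model with the block held by construction. No trend on span was added to the group effects. The shares below hold for that setting only. In the knockdown comparison limma without the block recovered 0, 6, 48 and 78% of genes changed 1.25, 1.5, 2 and 3-fold with 0 false calls, limma with the block 61.2, 72, 90 and 100% with 6.4% of calls false, and DESeq2 with the block on 6 libraries 36, 52, 74 and 84% with 0 false. In the agonist comparison limma with the block had 8.82% of calls false.

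29 gene lists were fixed before the data were examined; 57 of their 556 symbols were not in the tables. Lists with at least 5 measured genes were tested with camera (preset inter-gene correlation 0.01, then an estimated one) and with fry, adjusted over the lists. Members were counted over all genes and adjusted over the list alone. Genes were named by a rule fixed beforehand: Ucp1, Ppargc1a, Dio2, Nr4a1, Adrb3, H2az1 and H2az2 always; the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 50 reads and no overlap of the groups, without predicted genes and small RNAs; and up to 4 members of each list by adjusted p. Since the unblocked knockdown test called none, the rule was applied to the letter-blocked calls there, a step chosen after the values were seen. Genes outside the rule, such as Esrrg, Cxcl10, Pparg, Prdm16 and Cd68, were named after their values were seen. A symbol on several entries takes the one with the highest mean.

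Gene spans and coordinates were taken from annotation of GRCm38.p6 (mm10), which matched 19007 entries (81.8%). A trend on span was removed from the log2 fold changes as an alternative, and a trend on the vehicle libraries' B minus A difference in the knockdown comparison. As strand is not stated, reads of overlapping or antisense genes may be counted together. The overlap of the comparisons was set against independent lists, against 100 simulated draws of unchanged groups with the same shared libraries, and against fold changes with no library in common. An interaction of knockdown and agonist could not be tested, as no vehicle-treated knockdown libraries were in the files.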

Results

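Nascent transcription was measured by PRO-seq, a run-on assay that maps engaged RNA polymerases in WT-1 cells, a mouse brown preadipocyte line that had been differentiated into brown adipocytes. The 6 libraries fell into 3 groups of 2: control adipocytes given vehicle, control adipocytes given the β3-adrenergic agonist CL316,243, and adipocytes with an shRNA against the histone variant H2A.Z given the agonist. Control cells carried a non-targeting shRNA, and vehicle or agonist was applied for 4 hours on day 11. Each group had a library A and a library B, after the letter in the column names. Reads in genes, in M (1e6 reads), came to 36.57 and 32.09 M in the vehicle libraries A and B, 35.08 and 35.1 M in the control agonist libraries, and 30.88 and 38.58 M in the knockdown libraries. The labels do not state separate cultures, so p-values measure only the spread between these samples, which may be technical. Library B differed from library A in the same genes in every group: the B minus A log2 differences correlated across 16068 genes with r = 0.65 between vehicle and control agonist, 0.639 between vehicle and knockdown, and 0.744 between control agonist and knockdown. Genes are not independent replicates. For this reason, values from a test without the letter (the unblocked test) are followed by those with the letter as a block (the letter-blocked test) where the block changed a call or moved a count by over 1.5 times, and for the gene lists throughout.

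The first comparison asked which genes changed their nascent transcription after 4 hours of agonist in control adipocytes. Ucp1, the uncoupling protein of brown fat thermogenesis, rose 10.7-fold, from 1295 ± 187 to 13824 ± 889 normalized counts (SD, n = 2; log2 fold change 3.42 ± 0.11, SE; limma adjusted p = 6.11e-05). The orphan nuclear receptor Nr4a1 rose by 2.62 ± 0.11 on the log2 scale, from 827 ± 26.1 to 5102 ± 724 (limma adjusted p = 8.47e-05). The coactivator gene Ppargc1a rose by 0.88 ± 0.09, from 13264 ± 575 to 24403 ± 2724 (limma adjusted p = 0.00152). Adrb3, which encodes the stimulated receptor, fell from 3124 ± 176 to 1049 ± 57.9 (log2 fold change -1.57 ± 0.09, limma adjusted p = 0.000177). Dio2, the activating thyroid hormone deiodinase, was transcribed at a low level, 9.45 ± 1.68 normalized counts with vehicle and 28.4 ± 6.83 with agonist, and passed the test at a log2 fold change of 1.48 ± 0.32 (limma adjusted p = 0.019). Of the genes for H2A.Z, H2az2 fell by 0.32 ± 0.08 (limma adjusted p = 0.0273), a call lost without the vehicle library A (-0.30) or B (-0.34), and H2az1 stood at -0.11 (limma adjusted p = 0.35). In coordinates of mm10, Ucp1 lies on chromosome 8 from 83290348 to 83298456, Ppargc1a on chromosome 5 from 51454249 to 52115853, and Adrb3 on chromosome 8 from 27225776 to 27230845.

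Of 19569 entries tested, 2075 were raised and 2167 lowered in the unblocked limma test, 495 and 356 of them at least 2-fold. The letter-blocked limma test called 5206 raised and 5245 lowered, and the authors' deposited table had 3537 and 3363. The genes with the highest fold changes were Fosl1, which encodes a subunit of the AP-1 transcription factor (log2 fold change 3.88 ± 0.11), the carbonic anhydrase gene Car9 (3.77 ± 0.15), the adenylyl cyclase gene Adcy3 (3.66 ± 0.14), the nuclear receptor gene Nr4a3 (3.62 ± 0.19), Ucp1, the cyclic nucleotide phosphodiesterase gene Pde10a (3.37 ± 0.13), the peptide hormone gene Adm2 (3.28 ± 0.19) and the receptor gene Gpr3 (3.12 ± 0.20). Their limma adjusted p ran from 6.11e-05 for Fosl1 to 0.00032 for Gpr3. Those with the lowest were Smim5 (-2.67 ± 0.20), the leptin gene Lep (-2.52 ± 0.14), Anxa8 (-2.36 ± 0.18), Abca8a (-2.16 ± 0.17), the angiopoietin gene Angpt1 (-2.13 ± 0.07), the BH3-only gene Bmf (-2.12 ± 0.13), Ly6h (-2.09 ± 0.19) and the elastin gene Eln (-2.08 ± 0.21). Angpt1 fell from 10059 ± 269.8 to 2296 ± 97.2 normalized counts (limma adjusted p = 6.11e-05). Without the vehicle library A the test called 1346 raised and 1427 lowered, and without the vehicle library B 1345 and 1197. With simulated data for this comparison, the unblocked test recovered 46.9% of genes changed 2-fold and 2% of those changed 1.5-fold over 19662 genes.

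**Figure D1:**
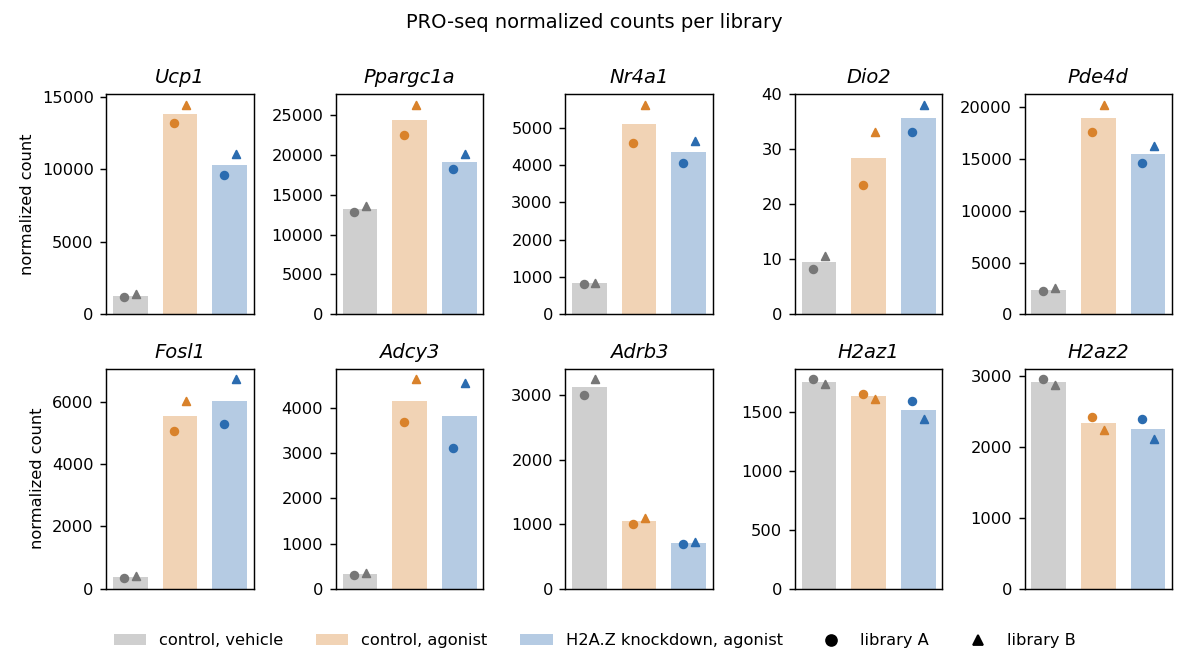
Normalized PRO-seq counts (vertical axes, linear from 0) of 10 genes in the 6 libraries. Bars are means of 2 libraries, circles library A and triangles library B. Ucp1 stood at 1295 with vehicle, 13824 with agonist and 10331 with knockdown and agonist, and H2az1 at 1760, 1634 and 1521.

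Gene lists fixed before the data were examined were described by their members and tested with limma's camera, which compares a list with all other genes. In the list of glucose uptake and glycolysis, 19 of 22 measured genes rose and 0 fell (20 raised adjusted over the list alone, 20 raised and 1 lowered letter-blocked), with a median log2 fold change of 1.15. Pfkp rose by 2.15 ± 0.12, the glucose transporter gene Slc2a1 by 1.55 ± 0.10, Eno1 by 1.51 ± 0.09 and Gapdh by 1.27 ± 0.07 (camera adjusted p = 5.57e-11; adjusted p = 0.323 with an estimated correlation). Of 20 targets of cAMP and its transcription factor CREB, 13 rose and 1, Rgs2, fell (14 and 1 adjusted over the list alone, 17 and 2 letter-blocked). Beside Nr4a1 and Nr4a3, the phosphodiesterase gene Pde4d rose by 2.99 ± 0.09, from 2378 ± 176 to 18927 ± 1854 (camera adjusted p = 9.68e-07; adjusted p = 0.269 with an estimated correlation). Among 19 thermogenic genes 11 rose and 1, Esrrg, fell (11 and 1 adjusted over the list alone, 13 and 3 letter-blocked): Ucp1, the hormone gene Fgf21 (2.04 ± 0.19), the fatty acid elongase gene Elovl3 (1.81 ± 0.14) and the glycerol kinase gene Gk (1.46 ± 0.08) were among the raised genes (camera adjusted p = 4e-04; adjusted p = 0.546 with an estimated correlation). Prdm16 and Ppara did not pass the unblocked test, at 0.09 (limma adjusted p = 0.658, 0.0473 letter-blocked, and 0.171 in the authors' deposited table) and -0.07 (limma adjusted p = 0.755).

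In the list of the respiratory chain and the tricarboxylic acid cycle, 15 of 31 genes rose and 0 fell, and 23 rose adjusted over the list alone; the letter-blocked test called 28 raised. Aco2 rose by 0.80 ± 0.08 and Cycs by 0.74 ± 0.07 (camera adjusted p = 1.57e-06; adjusted p = 0.269 with an estimated correlation). Fatty acid oxidation had 11 raised genes and 1 lowered of 27 (12 and 1 adjusted over the list alone, 17 and 2 letter-blocked), among the former the thioesterase gene Acot2 (1.53 ± 0.11) and the carnitine palmitoyltransferase gene Cpt1a (1.00 ± 0.08; camera adjusted p = 0.000398; adjusted p = 0.546 with an estimated correlation). Of 18 cholesterol synthesis genes 11 rose and 0 fell (13 and 2 adjusted over the list alone, 15 and 2 letter-blocked), among them Sqle (0.88 ± 0.07), Hmgcs1 (0.71 ± 0.07) and Hmgcr (0.67 ± 0.07; camera adjusted p = 0.000134; adjusted p = 0.269 with an estimated correlation). The heat shock list had 8 raised and 0 lowered of 14 (10 and 0 adjusted over the list alone, 12 and 0 letter-blocked), including the co-chaperone gene Bag3 (0.89 ± 0.07; camera adjusted p = 0.000134; adjusted p = 0.269 with an estimated correlation). The list of the integrated stress and unfolded protein responses had 12 raised and 3 lowered of 22 (14 and 3 adjusted over the list alone, 16 and 4 letter-blocked), with Ddit4 at 1.38 ± 0.11 and Trib3 at 1.26 ± 0.08 (camera adjusted p = 0.000433; adjusted p = 0.269 with an estimated correlation). Camera also called mitochondrial biogenesis (7 raised, 2 lowered of 19; adjusted p = 0.0302), inflammation (4 and 0 of 15, with Cxcl1 at 1.09 ± 0.11; adjusted p = 0.0146), ribosome biogenesis (5 and 0 of 18; adjusted p = 0.0311) and the housekeeping genes (7 and 0 of 15, with the glycolytic Pgk1 at 1.86 ± 0.12; adjusted p = 0.0012) as higher. With an estimated correlation their calls were lost, at an adjusted p = 0.323, 0.39, 0.561 and 0.269 in that order. Adjusted over the list alone, these 4 lists had 11, 5, 6 and 10 raised and 3, 0, 1 and 0 lowered members. Letter-blocked they had 13, 7, 8 and 12 raised and 4, 0, 1 and 1 lowered. The median log2 fold change was 0.264 for the respiratory chain, 0.22 for fatty acid oxidation and 0.222 for mitochondrial biogenesis. The housekeeping genes had 0.245, so shifts of that size were not particular to these lists. Cholesterol synthesis, heat shock and stress responses had 0.34, 0.302 and 0.31. With 1 library left out, camera did not call mitochondrial biogenesis without vehicle A (adjusted p = 0.199), vehicle B (0.144), control agonist A (0.0539) or control agonist B (0.115), ribosome biogenesis without vehicle B (0.227) or control agonist A (0.0927), or inflammation without control agonist B (0.115).

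4 lists were lower after agonist. Adipocyte identity genes fell in 12 of 20 cases with 0 raised (12 and 1 adjusted over the list alone, 15 and 2 letter-blocked), among them Lep, Adrb3, the adipsin gene Cfd (-1.18 ± 0.07) and the transcription factor gene Zfp423 (-0.85 ± 0.08; camera adjusted p = 6.65e-05; adjusted p = 0.328 with an estimated correlation), while Pparg stood at -0.06 (limma adjusted p = 0.709). Of 22 cell cycle genes 9 fell and 0 rose (10 adjusted over the list alone, 15 letter-blocked), with Cdk1 at -0.51 ± 0.07 and Top2a at -0.42 ± 0.08 (camera adjusted p = 0.000993; adjusted p = 0.269 with an estimated correlation). Interferon-stimulated genes had 8 lowered members and 1 raised, Cxcl10, of 21 (9 and 1 adjusted over the list alone, 12 and 2 letter-blocked), among them Ifit3 (-1.17 ± 0.16) and Gbp2 (-1.10 ± 0.12; camera adjusted p = 0.00242; adjusted p = 0.269 with an estimated correlation). Fibroblast, preadipocyte and matrix genes had 4 lowered and 1 raised of 20 (5 and 1 adjusted over the list alone, 12 and 3 letter-blocked), with Sparc at -0.55 ± 0.08 and Fn1 at 0.41 ± 0.08 (camera adjusted p = 0.0311; adjusted p = 0.537 with an estimated correlation). Other lists held members that moved without a camera call. Adrenergic signalling had 9 raised and 3 lowered of 25 (13 and 7 letter-blocked; camera adjusted p = 0.106), with Adcy3 and Pde4d up and Adrb3 and Rgs2 down. The clock genes had 9 raised and 5 lowered of 19 (11 and 7; 0.27), with Ciart at 1.59 ± 0.10 and Per3 at -0.89 ± 0.08. Creatine and calcium cycling had 5 and 1 of 9 (6 and 2; 0.0606), with Alpl at 2.24 ± 0.10 and Gamt at -0.81 ± 0.12. Lipolysis and lipid droplet genes (5 raised, 3 lowered of 16), with the droplet coat gene Plin2 at 1.35 ± 0.10 and Aqp7 at -0.79 ± 0.13, lipogenesis (6 and 4 of 21) and secreted factors (7 and 6 of 17), with the retinol carrier gene Rbp4 at 2.16 ± 0.07, were not called by camera (adjusted p = 0.27, 0.519 and 0.58). Letter-blocked they had 7 and 5, 9 and 8, and 8 and 6. Nor were p53 targets (4 and 5 of 17; adjusted p = 0.546), elongation control (4 and 0 of 22; 0.127), H2A.Z deposition and removal (3 and 1 of 20; 0.827), chromatin loop factors (0 and 2 of 18; 0.315) or replication histones (0 and 0 of 7; 0.158). Letter-blocked, H2A.Z deposition and removal had 4 raised and 6 lowered, loop factors 3 and 9, replication histones 0 and 4, p53 targets 8 and 6 and elongation control 10 and 1. Without the vehicle library B, Top2a and Fn1 did not pass limma's test (-0.37 and 0.40), and camera did not call the matrix list (adjusted p = 0.11, and 0.0927 without the control agonist library A). Markers of other cell types were measured at 3 genes, Cd68, Pecam1 and Acta1, and 0 passed limma's unblocked test, while Cd68 passed the letter-blocked one (0.18, limma adjusted p = 0.00622, and 0.133 in the authors' deposited table).

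**Figure D2:**
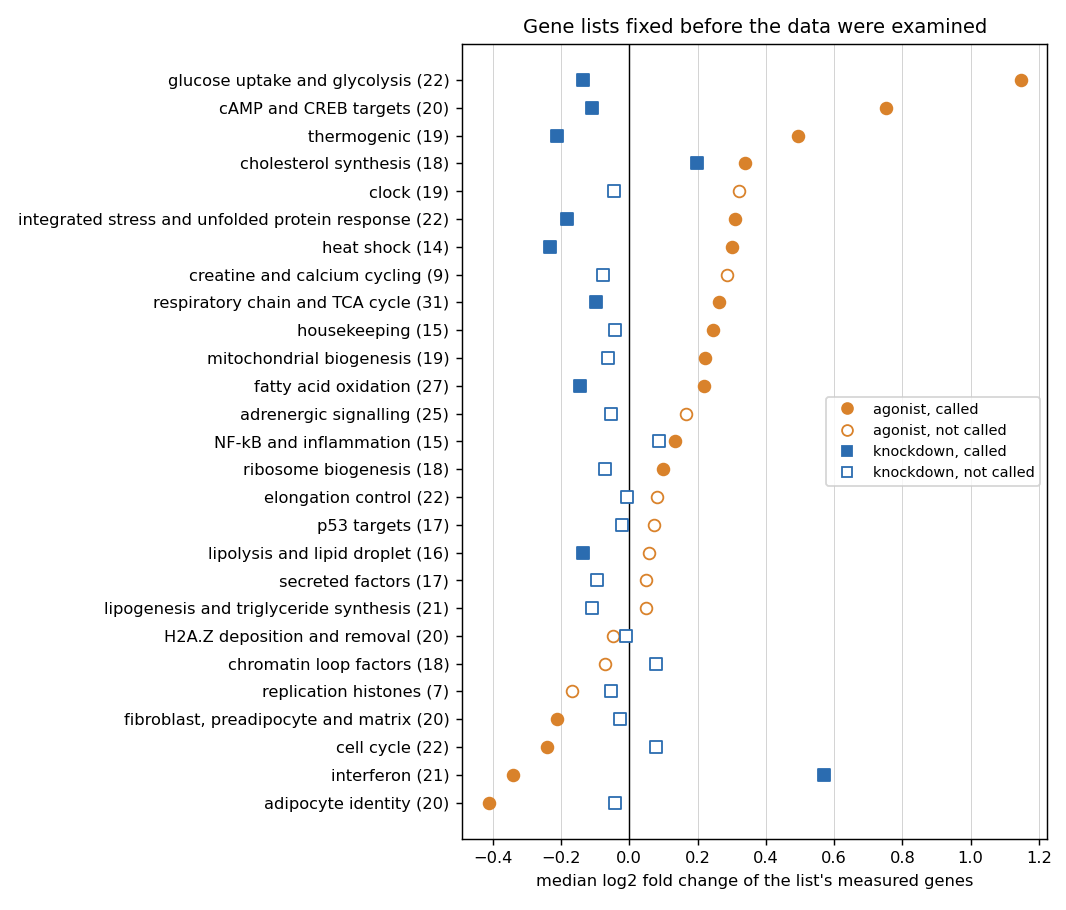
Median log2 fold change (horizontal axis) of each of 27 gene lists, with the number of genes measured in the agonist comparison in parentheses. Circles are agonist against vehicle and squares knockdown against control under agonist; filled symbols passed camera with a preset correlation, and none passed with an estimated one. Glycolysis stood highest after agonist at 1.15, and the interferon list highest in knockdown at 0.57.

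The second comparison set H2A.Z knockdown against control, both under agonist. Nascent transcription of the target genes differed little: H2az1 stood at 1653 and 1615 normalized counts in the control agonist libraries A and B and at 1597 and 1445 in the knockdown libraries (log2 fold change -0.11 ± 0.09, limma adjusted p = 0.756, 0.0557 letter-blocked). H2az2 stood at 2418 and 2239 in control and at 2397 and 2113 in knockdown (-0.05 ± 0.10, limma adjusted p = 0.881, 0.367 letter-blocked). With vehicle, H2az1 stood at 1780 and 1740 and H2az2 at 2952 and 2864. An shRNA acts on finished mRNA, which PRO-seq does not measure, so these values do not check the knockdown.

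Without the letter, limma called 0 of 19617 entries (1260 at an unadjusted p under 0.05, smallest adjusted p = 0.504), edgeR called 0 and DESeq2 59 raised and 9 lowered (115 and 29 on all 6 libraries). With the letter as a block, limma called 2756 raised and 4138 lowered, 257 and 180 of them at least 1.5-fold, and edgeR 2972 and 3876. The authors' deposited table, whose statistics come from a model with the letter, had 952 raised and 1247 lowered. In the letter-blocked test 20 of 21 interferon-stimulated genes rose and 13 of 19 thermogenic genes fell (camera letter-blocked adjusted p = 1.1e-08 and 0.00128; adjusted p = 0.686 for both with an estimated correlation). The antiviral gene Mx2 rose from 479 ± 26.8 to 1280 ± 420 normalized counts (SD, n = 2; log2 fold change 1.38 ± 0.06, SE; limma letter-blocked adjusted p = 6.76e-59, 0.504 unblocked), and Ucp1 fell from 13824 ± 889 to 10331 ± 1065 (-0.42 ± 0.03; limma letter-blocked adjusted p = 3.03e-38, 0.626 unblocked). Ppargc1a fell by 0.34 ± 0.02 on the log2 scale (2.67e-31, 0.747 unblocked), Adrb3 by 0.57 ± 0.06 (1.17e-17, 0.504 unblocked) and Nr4a1 by 0.23 ± 0.03 (4.05e-10, 0.747 unblocked), in letter-blocked limma adjusted p. Dio2 stood at 28.4 ± 6.83 and 35.7 ± 3.44 (limma letter-blocked adjusted p = 0.349, 0.749 unblocked). Letter-blocked standard errors and p-values rest almost wholly on spread borrowed from other genes, not on a gene's own libraries. The authors' deposited standard error was 0.233 for Mx2 and 0.0476 for Ucp1.

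By the same naming rule, applied to the letter-blocked calls after the values were seen, the genes with the highest fold changes in knockdown were Ifi44 (1.62 ± 0.15), Apol9b (1.53 ± 0.16), Iigp1 (1.46 ± 0.22), Ly6a (1.38 ± 0.17), Mx2, Apol9a (1.37 ± 0.13), Ifit3b (1.33 ± 0.13) and Ifit3 (1.19 ± 0.12). Apol9a and Apol9b, and Ifit3 and Ifit3b, are close paralogs whose reads may be shared. Ifit3 stood at 283 ± 40.3 with vehicle, 124 ± 3.43 with agonist and 287 ± 52.0 in knockdown with agonist. The lowest were Plac8 (-1.57 ± 0.22), the BMP antagonist gene Grem1 (-1.24 ± 0.16), Rgs16 (-1.23 ± 0.20), Ccn5 (-1.05 ± 0.09), Fgf21 (-1.02 ± 0.14), the fibrillin gene Fbn1 (-0.93 ± 0.05), Rspo2 (-0.88 ± 0.10) and Serpinf1 (-0.86 ± 0.20). Fbn1 stood at 1565 ± 30.7 in control and 824 ± 123 in knockdown (limma letter-blocked adjusted p = 4.46e-45, 0.504 unblocked). In the authors' deposited table Fbn1 had a log2 fold change of -0.93 (adjusted p = 2.88e-18), Mx2 1.39 (2.6e-07), Ucp1 -0.42 (5.4e-16) and Ppargc1a -0.34 (3.28e-13). Ifi44, Apol9b, Iigp1, Ly6a, Plac8, Rgs16, Fgf21 and Serpinf1 had no adjusted p there. Standard errors there were larger than the letter-blocked ones, such as 0.275 for Ifi44 and 0.667 for Iigp1.

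**Figure D3:**
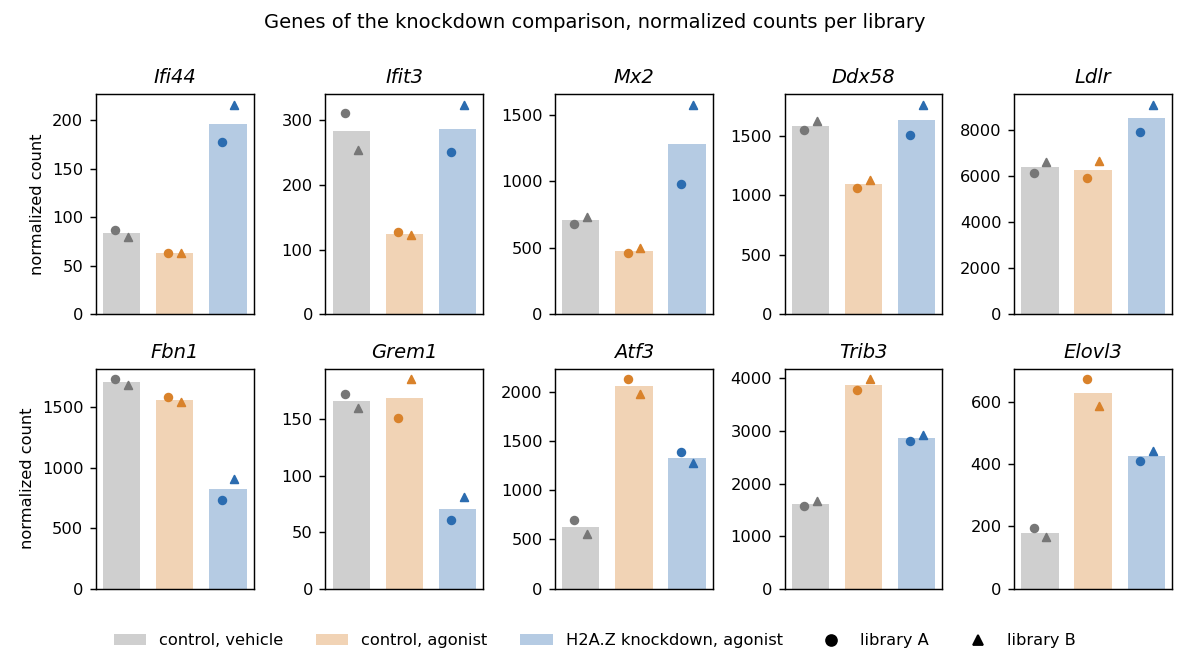
Normalized PRO-seq counts (vertical axes, linear from 0) of 10 genes of the knockdown comparison in the 6 libraries. Bars are means of 2 libraries, circles library A and triangles library B. Mx2 stood at 479 in control and 1280 in knockdown under agonist, and Fbn1 at 1565 and 824.

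The interferon list was higher in knockdown, with all 21 measured genes above control and a median of 0.57 (camera adjusted p = 4e-16; adjusted p = 0.449 with an estimated correlation). It was not called by fry (adjusted p = 0.18 unblocked and 0.182 letter-blocked). Unblocked fry called 0 of 27 lists in knockdown. Letter-blocked fry called 2, thermogenic genes (adjusted p = 0.0197) and stress responses (0.0206). Of the interferon genes, 20 rose letter-blocked and 0 unblocked over all genes, and 20 and 14 rose adjusted over the list alone. The authors' deposited table had 11 raised. The RNA sensor genes Ifih1 and Ddx58 rose by 0.76 ± 0.06 and 0.57 ± 0.05 letter-blocked (limma adjusted p = 1.09e-26 and 2.34e-24). Cholesterol synthesis was also higher (median 0.20; camera adjusted p = 1.12e-05; adjusted p = 0.439 with an estimated correlation), with 16 of 18 genes raised letter-blocked, over all genes and adjusted over the list alone, and 0 unblocked. They included the low-density lipoprotein receptor gene Ldlr (0.44 ± 0.03) and Fdps (0.40 ± 0.04), and the authors' deposited table had 13 raised.

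8 lists were lower by camera. Letter-blocked calls over all genes came to 13 lowered of 19 thermogenic genes, 9 of 14 heat shock genes, 15 of 22 stress response genes and 12 of 20 cAMP and CREB targets, with 0, 0, 0 and 3 raised, and unblocked limma called 0 in each. The authors' deposited table, a DESeq2 test, had 10, 9, 10 and 5 lowered and 0 raised. Adjusted over the list alone, the letter-blocked counts were 13, 9, 17 and 12 lowered and 0, 0, 2 and 3 raised, and the unblocked ones 4, 2, 4 and 1 lowered and 0 raised. Their camera adjusted p = 0.000418, 0.00011, 0.00011 and 0.0221, and adjusted p = 0.73, 0.439, 0.439 and 0.449 with an estimated correlation. Beside Ucp1 and Ppargc1a, the coactivator gene Ppargc1b and the receptor gene Ppara fell by 0.29 ± 0.02 and 0.29 ± 0.03. Hspa1a fell by 0.53 ± 0.06 (its near-identical copy Hspa1b by 0.42 ± 0.04), Trib3 by 0.43 ± 0.04, Cth by 0.46 ± 0.04 and Atf3 by 0.62 ± 0.04, all letter-blocked. Without the control agonist library B or the knockdown library A, camera did not call thermogenic genes (adjusted p = 0.237 and 0.197) or cAMP and CREB targets (0.239 and 0.175). Fos and Nr4a3, at -0.52 ± 0.05 and -0.44 ± 0.05, passed the letter-blocked limma test (adjusted p = 1.05e-21 and 4.44e-13) but had an adjusted p of 0.267 and 0.312 in the authors' deposited table.

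Fatty acid oxidation had 17 of 27 genes lowered letter-blocked, among them Acsl1 (-0.25 ± 0.02) and Hadhb (-0.23 ± 0.03). The respiratory chain and tricarboxylic acid cycle had 18 of 31, among them Aco2 (-0.23 ± 0.03). Glycolysis had 17 of 22, among them Ldha (-0.19 ± 0.02), and lipolysis 10 of 16, among them G0s2 (-0.29 ± 0.03). Raised letter-blocked were 1, 0, 1 and 3 in these lists, and unblocked limma called 0 in each. The authors' deposited table had 14, 8, 11 and 7 lowered and 0, 0, 0 and 1 raised. Adjusted over the list alone, 17, 19, 17 and 10 were lowered and 1, 0, 1 and 3 raised letter-blocked. Camera gave adjusted p = 0.000561, 0.00194, 0.00574 and 0.026 for these lists, and adjusted p = 0.73, 0.439, 0.73 and 0.73 with an estimated correlation. Without the control agonist library B their adjusted p values were 0.239, 0.237, 0.632 and 0.632, and without the knockdown library A 0.519, 0.336, 0.731 and 0.776. With the block, the call of lipolysis was lost (camera adjusted p = 0.0869), and cell cycle and inflammation were called as higher (0.0397 and 0.0461; adjusted p = 0.686 for both with an estimated correlation), with 7 raised and 2 lowered, and 6 raised and 3 lowered (3 and 0, and 1 and 1, in the authors' deposited table), among them Aurka at 0.23 ± 0.05 and Cxcl1 at 0.48 ± 0.06. Members of other lists were called letter-blocked without a camera call. The letter-blocked test called 2756 raised and 4138 lowered of all 19617 entries, so such counts do not by themselves show that a list moved. Matrix genes had 7 raised, among them Col5a1 (0.39 ± 0.04), and 6 lowered, among them Pdgfra (-0.86 ± 0.10), and p53 targets 4 raised, with Eda2r at 0.92 ± 0.08, and 4 lowered. Adipocyte identity genes had 7 raised, with Zfp423 at 0.22 ± 0.03, and 9 lowered, with Cebpb at -0.28 ± 0.03. Raised and lowered letter-blocked counts were 2 and 10 for adrenergic signalling, 3 and 13 for lipogenesis, 3 and 9 for secreted factors, 1 and 8 for mitochondrial biogenesis, 3 and 5 for the clock, 2 and 4 for creatine and calcium cycling, 3 and 4 for ribosome biogenesis, 5 and 4 for H2A.Z deposition and removal, 9 and 3 for chromatin loop factors, 3 and 3 for elongation control (1 and 1 adjusted over the list alone), 0 and 4 for housekeeping and 0 and 2 for replication histones. Unblocked limma called 0 in each. The authors' deposited table, a DESeq2 test, had for these 12 lists, in the same order, 0 and 7, 2 and 9, 2 and 4, 1 and 2, 0 and 3, 2 and 0, 1 and 1, 0 and 0, 2 and 0, 0 and 0, 0 and 1, and 0 and 0. For matrix genes it had 3 and 4, for p53 targets 3 and 1, and for adipocyte identity 6 and 7. Of the 3 markers of other cell types, the macrophage gene Cd68 passed the letter-blocked test (0.23, limma adjusted p = 2.29e-05, 0.759 unblocked, and 0.0635 in the authors' deposited table).

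The knockdown fold changes ran with gene span and with a difference between libraries of one group. Their median was -0.12 in library A and -0.13 in library B over the shortest of 5 equal groups of genes by span and 0.07 and 0.06 over the longest, and the vehicle libraries' own B minus A difference ran from -0.08 to 0.06. Across 16068 genes the knockdown fold change correlated with that vehicle difference with r = 0.384, and in libraries A and B with each other with r = 0.69. With a trend on span removed, 68.4% of the 6134 letter-blocked knockdown calls with a known span were called in the same direction, against 94.1% of 9224 agonist calls. The 2 shares are not like for like. Letter-blocked knockdown calls were smaller, with a median absolute log2 fold change of 0.203, against 0.347 for agonist calls. With the span trend removed, camera's letter-blocked adjusted p in knockdown rose for the respiratory chain (0.000711 to 0.0458) and stress responses (0.00061 to 0.0106). It also rose for heat shock (0.000711 to 0.00958), glycolysis (0.00463 to 0.0121) and cAMP and CREB targets (0.0209 to 0.0333). For thermogenic genes it fell (0.00128 to 7.32e-05), and for fatty acid oxidation it stayed near its value (0.00061 and 0.000602). Leaving out 1 library at a time, the unblocked test called 30 raised and 5 lowered without the control library A, 68 and 36 without the control library B, 147 and 213 without the knockdown library A, and 5 and 13 without the knockdown library B. In simulated data for this comparison over 19654 genes, the unblocked limma test recovered 48% of genes changed 2-fold and 6% of those changed 1.5-fold, and the letter-blocked one 90% and 72%, with 6.4% of its calls false. The simulated letter difference was the same in every group, so that share does not measure false calls among the letter-blocked calls of the data.

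**Figure D4:**
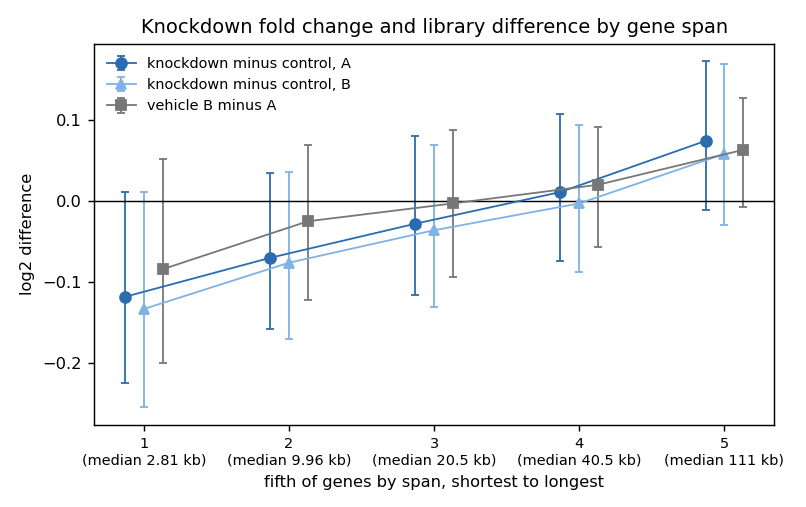
Median log2 difference (vertical axis) with quartiles as bars, over 5 equal groups of genes ordered by span (horizontal axis). Blue symbols are knockdown minus control in library A (circles) and library B (triangles), and grey squares the vehicle library B minus A. All 3 series rise from the shortest to the longest genes, the grey one from -0.08 to 0.06.

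The last comparison asked whether genes raised by the agonist were lower in knockdown. Of the 2075 genes raised in the unblocked agonist test, 0 were also lowered in the unblocked knockdown limma test, which called none (1260 at an unadjusted p under 0.05; edgeR also shared 0). Leaving out 1 library, 20 were shared without the control agonist library B, 18 without the knockdown library A, 4 without the knockdown library B and 1 without the control agonist library A. In the letter-blocked tests 1844 genes were raised by agonist and lowered in knockdown, where independent lists would share 1111, and 492 were raised in both, where independent lists would share 737.3. Ucp1, Ppargc1a, Pde4d, Nr4a1, Nr4a3, Atf3, Trib3, Elovl3 and Fgf21 were among the 1844. In the opposite direction 1460 genes were lowered by agonist and raised in knockdown, where independent lists would share 735.6, among them Ifit3, Mx2, Ddx58, Gbp2 and Zfp423. In the authors' deposited table, a total of 524 genes were raised and then lower (independent lists, 287.6) and 559 lowered and then higher (214.1). Fosl1 and Car9 were among the 492 genes raised in both, at 0.11 and 0.16 in knockdown (limma letter-blocked adjusted p = 0.00184 and 0.0367, but 0.176 and 0.432 in the authors' deposited table). Pde10a was not called in knockdown (-0.05, limma letter-blocked adjusted p = 0.299, and 0.685 in the authors' deposited table).

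Both fold changes use the control agonist libraries with opposite sign, so part of the excess over independent lists may come from them. Across 16068 genes the fold changes correlated with r = -0.235. Simulated unchanged groups with the same shared libraries gave r = -0.501, a value set by the sharing alone. The 2 values are not like for like, as the data also hold changes made by the agonist, which the simulation left out. The covariance was -0.0212 against -0.00403 simulated, a difference of -0.0172. The simulated covariance depends on the spread used, which was that of the letter-blocked fit on all 6 libraries. With no library shared, r was -0.204 for the agonist effect in library A against the knockdown effect in library B, and -0.154 the other way round. There, 62.7% of 351 genes raised at least 2-fold in A were lower in knockdown in B, against 57.4% of 15473 genes changed less than 2-fold, and 31.6% of 244 genes lowered at least 2-fold. The other way round these shares were 67.7% of 375, 53.9% of 15424 and 33.5% of 269. No knockdown group with vehicle was analysed here, so whether the knockdown changed the response to the agonist could not be separated from a change already present without it.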

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

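Alternatives, a replicate block among them, were listed before the data were examined. Chosen after the data were seen were edgeR with TMM on recovered reads, the column letter as the source of the block, the block on 6 libraries, with edgeR, DESeq2 or fry, the span trend and the vehicle B minus A trend. No list or named gene called in the unblocked test changed direction. Ones not called in that test did in knockdown: named genes numbering 4 with block and span trend removed, 6 without the control agonist library A and 4 without the knockdown library B, and, with block and span trend removed, the elongation control, housekeeping, replication histone and ribosome biogenesis lists. The letter-blocked test left 3 named genes uncalled in knockdown, so the 4 were not all uncalled in it. The authors' own normalization is that of the tested values, and the alternative with a different control agonist library for each fold change is given as correlations (-0.204 and -0.154 against -0.235). Where a value below differs, the cause was not tested, apart from the fold minimum, which by construction keeps fewer genes. Leaving out a library leaves fewer samples, but this does not account for the direction of all changes. Agonist calls fell without the vehicle library A or B and rose without the control agonist library A or B. Knockdown calls rose whichever library of that comparison was left out. With 2 libraries per group, limma without a block recovered 46.9% (agonist) and 48% (knockdown) of genes changed 2-fold in simulated data.

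Against 2075 genes raised and 2167 lowered by agonist, other scalings, filters, pseudocounts and tools without a block gave 1685 to 2129 raised and 1962 to 2515 lowered. With at least 1.5-fold 1022 and 1060 were left, and the authors' deposited table had 3537 and 3363. The replicate block by letter gave 5206 and 5245, on 6 libraries 5110 and 5073, with edgeR 4877 and 5483, with DESeq2 on 6 libraries 3537 and 3363, and with the span trend removed 4832 and 4437. Leaving out 1 library gave 1345 to 2798 raised and 1197 to 2979 lowered.

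In knockdown, 0 were called without a block in limma under each scaling, filter and pseudocount tried and in edgeR under 3 scalings. DESeq2 without the letter called 59 raised and 9 lowered on 4 libraries and 115 and 29 on 6, and the authors' deposited table had 952 and 1247. The replicate block by letter gave 2756 and 4138, on 6 libraries 2149 and 3234, with edgeR 2972 and 3876, with DESeq2 on 6 libraries 952 and 1247, with the span trend removed 2341 and 2718, and with the vehicle B minus A trend removed 2339 and 2439. Leaving out 1 library gave 5 to 147 raised and 5 to 213 lowered. Genes raised by agonist and lower in knockdown numbered 0 unblocked, 524 in the authors' deposited table, 1844 with the replicate block, 1376 with block and span trend removed, and 0 to 20 with 1 library left out.

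Of the gene lists, 16 were called by agonist, 0 with an estimated correlation, 13 with fry, 16 with the replicate block, 18 with block and span trend removed (creatine and calcium cycling, adjusted p = 0.0389, and replication histones, 0.00933, were gained) and 14 to 16 with 1 library left out. In knockdown 10 were called, 0 with an estimated correlation, 0 with fry, 11 with the replicate block, 12 with block and span trend removed (lipogenesis, 0.0238, was gained), 2 with block and fry, and 4 to 12 with 1 library left out (4 without the control agonist library B, 5 without the knockdown library A). The block changed no other list call than those printed beside the lists. After agonist, unblocked fry did not call thermogenic genes (adjusted p = 0.0594), fatty acid oxidation (0.0537), matrix genes (0.0669) or ribosome biogenesis (0.0735). Of the named genes in the agonist comparison, 124 stayed on their side of the threshold with DESeq2 and 3 lost their call, and 20 and 22 lost it without the vehicle library A or B. In knockdown 18 gained a call with DESeq2 without a block, and 8 to 29 with 1 library left out and no block. With the replicate block 134 gained one. That number follows largely from naming genes by their letter-blocked calls, so it does not measure how well the calls hold.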

Other observations

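2 more gene groups were written after the highest genes of the agonist comparison and results of the fixed lists had been seen. The tests over members in no fixed list were chosen after the other results were seen. Camera p-values of both groups are not adjusted, so they cannot be set against the adjusted ones of the fixed lists. Targets of hypoxia-inducible factor (HIF) were higher after agonist: 33 of 36 rose and 1, the lipase inhibitor gene Angptl4 (-0.47, limma adjusted p = 0.00543), fell (33 and 2 letter-blocked), with a median log2 fold change of 1.36. Beside Car9, the adenylate kinase gene Ak4 rose by 2.56 ± 0.12, Ndrg1 by 2.16 ± 0.08, the oxidoreductase gene Ero1l by 2.14 ± 0.07, the HIF prolyl hydroxylase genes Egln3 and Egln1 by 1.74 ± 0.11 and 1.35 ± 0.11, and Vegfa by 0.59 ± 0.10, while Pfkfb4 (-0.17, limma adjusted p = 0.175, 0.0063 letter-blocked) and Aldoc (-0.07, 0.818) did not pass the unblocked test. Of the 36, 9 were also in the glycolysis list, 14 in any fixed list and 9 had been seen. Over the 27 not seen one by one 24 rose (camera p = 5.4e-14, and p = 0.137 with an estimated correlation), but some of these belonged to fixed lists that had been tested. Over the 15 neither seen nor in a fixed list 13 rose and 0 fell (median 1.06, camera p = 2.86e-09, and p = 0.121 with an estimated correlation). In knockdown 23 of the 36 were lowered and 3 raised letter-blocked, and 0 unblocked in limma (median -0.11, camera p = 0.00154, and p = 0.482 with an estimated correlation).

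Feedback and immediate targets of the ERK kinase pathway also rose after agonist, 13 of 21 measured with 0 lowered (15 and 2 letter-blocked, median 0.65). The ERK phosphatase genes Dusp5, Dusp4 and Dusp6 rose by 2.16 ± 0.08, 0.87 ± 0.08 and 0.79 ± 0.14, the transcription factor gene Etv5 by 2.02 ± 0.10, and the pathway inhibitor genes Spred2 and Spry4 by 1.69 ± 0.09 and 1.32 ± 0.07, while Spry1 (-0.07) was not called and Myc (-0.21) passed only the letter-blocked of the 2 limma tests (adjusted p = 1.79e-06, 0.0669 unblocked). Over the 18 members that had not been seen one by one, 10 rose (camera p = 1.59e-05, and p = 0.0429 with an estimated correlation), and over the 15 of these in no fixed list 9 rose (median 0.63, camera p = 8.76e-06, and p = 0.0416 with an estimated correlation). In knockdown 5 of the 21 were raised and 6 lowered letter-blocked, and 0 unblocked in limma (median -0.03, camera p = 0.868, and p = 0.872 with an estimated correlation).

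Of the tests below, that of shared libraries was written after the result was seen, and the column letter as the source of the planned replicate block, the span trend and the library difference were chosen after the data were seen. The first pattern is that knockdown fold changes ran with the vehicle libraries' B minus A difference. Gene span could account for it, but with the span trend removed from both r was 0.313 across genes, which are not independent replicates, so span alone is unlikely to be the cause. A difference in library quality unrelated to knockdown is left open: with that trend removed 56.5% of letter-blocked calls were called in the same direction. Repeat libraries made in another order might separate the 2.

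The second pattern is that agonist-raised genes were lower in knockdown. Shared control agonist libraries could give it. With no library in common the weaker correlation across genes was -0.154, and with the span trend also removed -0.139. Noise of single libraries or span is therefore unlikely to be the whole cause. A deviation that both control agonist libraries have in common would remain in these correlations. The library difference of the first pattern was not removed here either, so both stay open. Whether the agonist-raised genes were already lower before agonist could not be tested.

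The third pattern is the higher interferon list in knockdown. The difference between the vehicle libraries is an unlikely cause. The list's median B minus A difference there was -0.07, against a knockdown median of 0.571. Span is also an unlikely cause, as the median was 0.57 with the span trend removed. The list's B minus A median was -0.013 in the control agonist libraries but 0.225 in the knockdown libraries. Its knockdown median was 0.443 in library A and 0.733 in library B, so the rise was seen in both and was larger in B. Whether a difference confined to the knockdown libraries adds to it was not tested. Exposure to the viral vector may have differed between the shRNAs, and 0 libraries had a measure of vector dose, so this stays open. The list's median after agonist was -0.34, in a comparison that uses the same control agonist libraries with opposite sign. The rise in knockdown is therefore not independent of that fall.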
